A study of Mus musculus with 4 samples.

How the data were processed

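Laser-captured mouse intestinal crypts were profiled on 4 single-colour expression arrays, 2 from control mice and 2 from mice with the beta-catenin gene deleted, at 2 days after induction. Per the labels, total RNA was isolated with a kit for small samples, its mRNA was amplified in 2 rounds, and the product was labelled with biotin. The deposited values are probe set intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes; the scaling target and software version are not given in the sources used here. MAS5 subtracts mismatch-probe signal, so that dim probe sets are noisy. Amplification shortens transcripts from the 5' end, and the 5' to 3' ratios of the control probe sets were therefore computed per array.

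The deposited table held 45101 probe sets. The 64 control probe sets were left out of all tests. Of the remaining 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Probe sets with several symbols were not used to name a gene. A check through the gene identifiers updated 0 symbols. Some genes of the lists have no probe set named for them alone and were not analysed here.

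The test, filter, pseudocount rule, scaling rule, gene lists, named-gene rule and most alternatives were chosen before the data were examined. Values were transformed as log2(intensity + 5), where 5 is the 20th percentile of all deposited values, rounded. Fold changes are on this scale, which understates the change of dim probe sets. Trimmed means (2% trimmed) of the deposited intensities were 130 and 130 in the controls and 169 and 111 in mutant replicates 1 and 2. Their largest ratio, 1.53, was beyond the limit of 10%, and quantile normalization was therefore applied to the log2 values by the rule set in advance. Array medians before scaling were 32, 21.1, 26.2 and 21.3 in the same order. Probe sets at or above the median (the 50th percentile) of mean log2 signal over all arrays were kept, which required a mean of at least 4.79 and left 22519 probe sets for 11395 genes.

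Mutant and control were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with an intensity trend, all 4 arrays and no covariate, two-sided, with Benjamini-Hochberg adjustment over all kept probe sets. There were 2 residual degrees of freedom and 6.4 prior degrees of freedom. Each error given as SE is that of the limma fit, except in the comparison of Paneth with stem cell genes. There the SE is computed from the spread over genes. A gene was represented by its probe set with the highest mean over all arrays, and disagreement in sign with its other kept probe sets is stated in the results.

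Gene lists (8 primary and 22 secondary, 30 in all) covered Wnt targets, crypt cell types, proliferation, signalling pathways, stress, immune and metabolic genes, and markers of other cell types that captured tissue could hold. They were tested in one family with camera at a preset correlation of 0.01, and again with camera's estimated correlation and with fry, which tests whether the genes of a set move on balance one way. Beside each list, genes were also adjusted over the list alone. Genes named in the text were Ctnnb1, a set of anchor genes, the 12 higher and 12 lower genes with non-overlapping groups taken by smallest p because fewer than 12 passed the test, and up to 4 members of each list with the smallest p. List members past the test may also be named.

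The pipeline was tested on simulated data modelled on this comparison, with 22519 probe sets, 2 arrays per group and 200 changed probe sets in each of 20 runs. The share of changed probe sets recovered was 0% at 2-fold, 19.9% at 4-fold, 61.5% at 8-fold and 85.9% at 16-fold, with 5.3 false calls per run. A list of 25 genes shifted by -0.8 was called in 20 of 20 runs, and 1 of 580 unshifted lists was called. The simulated genes varied independently, whereas the estimated correlation in the real lists was, for example, 0.741 for mitosis and 0.392 for replication. The simulated share of false list calls therefore does not carry over to these lists.

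Alternatives covered the values as deposited, median centring, other pseudocounts, other filters, no intensity trend, robust estimation, a block for the replicate number, leaving out each array, other list tests, the mean of all probe sets of a gene, and non-overlapping groups with a 2-fold difference and no p. Overlap between lists and the array with pancreatic transcripts were examined after the data had been seen.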

Results

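Transcript levels were measured in epithelial crypts of the mouse intestine, the pockets that house stem cells, Paneth cells and dividing progenitors, which had been cut out of tissue by laser capture microdissection. Crypts of control mice were compared with crypts of mice in which the beta-catenin gene had been deleted by tamoxifen, 2 days after induction. The RNA went through 2 rounds of amplification before hybridisation, and each group held 2 arrays. The labels do not say whether the samples of a group came from separate mice. The limma p-values therefore measure only the spread between these samples, which may be technical. The camera p-values at the preset correlation of 0.01 set the genes of a list against the other genes. They take genes as nearly independent and are not a measure of how a list mean varies between samples. The number of arrays limits the precision of every value. Over the probe sets kept by the filter, the correlation between arrays was 0.932 within the controls, 0.918 within the mutants and between 0.912 and 0.936 across groups. It is across probe sets, which are not independent replicates. The 5' to 3' signal ratio of the beta-actin control, a sign of RNA length, was 0.149 and 0.0567 in control replicates 1 and 2 and 0.0945 and 0.0448 in mutant replicates 1 and 2. The library of mutant replicate 1 also held high levels of pancreatic enzyme transcripts, with a mean log2 signal of 12.42 over 10 such genes against 4.47, 4.55 and 4.13 in control 1, control 2 and mutant 2. For that reason each gene list that passed is also given without mutant replicate 1.

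The deleted gene was examined first. Ctnnb1 encodes beta-catenin, the transcriptional co-activator of the Wnt pathway and a component of adherens junctions. Its brighter probe set (1420811_a_at) had a log2 signal of 12.50 ± 0.09 (SD, n = 2) in controls and 11.94 ± 0.11 (SD, n = 2) in mutants, a difference of -0.56 (SE 0.22, 1.48-fold lower), with both mutant values below both control values. This difference did not pass the test over all probe sets (limma, adjusted p = 0.785). The deposited signals of this probe set were 4700 and 5997 in the controls and 5229 and 3449 in the mutants. A dimmer probe set (1450008_a_at) differed in the opposite direction, by 0.38 (SE 0.50). The labels do not say which exons were deleted, and a probe set outside the deleted part checks nothing about the labels.

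Genes activated by Wnt signalling were lower in the mutant crypts as a group. Of 21 measured Wnt/beta-catenin target genes, 19 were lower and 2 higher, and the list fell by 0.75 on the log2 scale on average (camera, adjusted p = 1.48e-08). The call was lost at adjusted p = 0.456 with an estimated correlation. Axin2, a feedback inhibitor of the pathway, had a log2 signal of 8.47 ± 0.80 (SD, n = 2) in controls and 6.55 ± 0.38 (SD, n = 2) in mutants, a difference of -1.92 (SE 0.46). The ubiquitin ligase gene Rnf43, which removes Wnt receptors, differed by -1.25 (SE 0.38) and the feedback inhibitor Nkd1 by -1.30 (SE 0.44). Of the 21 genes, 0 passed when adjusted over the list alone and 0 over all probe sets. Of other classical targets, the value was -0.56 (SE 0.36) for Myc, -0.55 (SE 0.39) for Sox9 with its other probe set at -1.29 (SE 0.49), -0.09 (SE 0.41) for Ephb3 and 0.02 (SE 0.33) for Cd44, whose other probe set had the opposite sign at -0.66 (SE 0.35). Ccnd1, the gene of cyclin D1, differed by -0.57 (SE 0.53) with 1 of its 2 other probe sets in the opposite direction. Without mutant replicate 1 the list stood at -0.67 (adjusted p = 2.6e-05). Adjusted over the list alone, 2 genes (Axin2 and Slc12a2) passed without control replicate 1 and 1 gene (Axin2) without mutant replicate 2.

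Markers of the stem cells at the crypt base were also lower. Of 25 measured stem cell genes, 24 were lower and 1 higher, and the list fell by 0.83 on average (camera, adjusted p = 4.06e-12). The corresponding value was adjusted p = 0.456 with an estimated correlation. Adjusted over the list alone, 6 genes fell (Olfm4, Axin2, Aqp4, Sox4, Slc12a2 and Rnf43), and over all probe sets 0 did. Olfm4, a secreted glycoprotein abundant in crypt base stem cells, fell 2.57-fold on the log2(signal + 5) scale, from 12.42 ± 0.14 (SD, n = 2) to 11.06 ± 0.19 (SD, n = 2), with an adjusted p of 0.0112 over the list alone by limma. The water channel gene Aqp4 fell by 1.52 (SE 0.36), with its other kept probe sets, both dimmer, at -0.27 (SE 0.57) and -0.10 (SE 0.46). The transcription factor gene Sox4 fell by 1.34 (SE 0.34), although 1 of its 2 other probe sets had the opposite sign. Lgr5, the R-spondin receptor that marks these stem cells, differed by -1.04 (SE 0.44), and the stem cell transcription factor gene Ascl2 by -0.73 (SE 0.39), with its other probe set at -1.23 (SE 0.39); neither gene passed. The Wnt target and stem cell lists shared 8 measured genes. With those left out, a choice made after seeing the data, the lists stood at -0.52 (13 genes, adjusted p = 0.00283) and -0.69 (17 genes, adjusted p = 1.07e-06). Without mutant replicate 1 the stem cell list stood at -0.71 (adjusted p = 3.44e-07), and 0 genes passed over the list alone; without control replicate 2, 3 did.

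**Figure D1:**
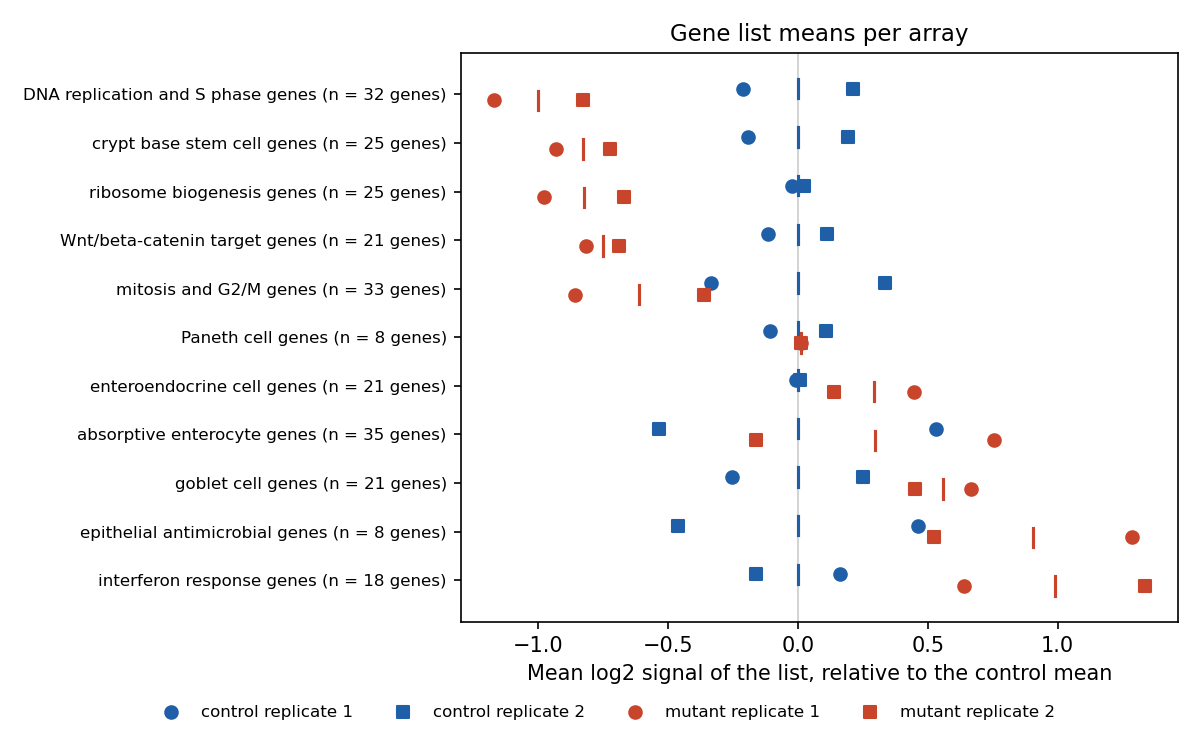
Mean log2 signal of 11 gene lists in each array (points) relative to the control mean, with vertical bars for the group means; n is the number of measured genes. The replication, stem cell, ribosome biogenesis and Wnt target means of both mutant arrays lie below both controls, whereas the enterocyte means of the groups overlap.

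Genes of DNA replication showed the lowest list mean among the 30 lists. All 32 measured replication and S phase genes were lower in the mutants, and the list fell by 0.999 on average (camera, adjusted p = 7.63e-21; adjusted p = 0.456 with an estimated correlation). Adjusted over the list alone, 11 genes fell, namely Mcm3, Mcm4, Mcm5, Mcm6 and Mcm7 of the replicative helicase, its loading factors Cdc6 and Cdt1, Gins1, Prim1, Rfc4 and Ccne2. Over all probe sets 0 genes passed. Mcm6 fell 3.57-fold, from a log2 signal of 10.24 ± 0.24 (SD, n = 2) to 8.41 ± 0.03 (SD, n = 2). The clamp loader gene Rfc4 fell by 1.65 (SE 0.37), and Mcm3 and Mcm5 by 1.58 (SE 0.35) and 1.23 (SE 0.31). With mutant replicate 1 left out the list stood at -0.82 with 30 of 32 genes lower (adjusted p = 4.23e-11). The number of genes passing over the list alone was then 0, and it was 19 without control replicate 1 and 2 without control replicate 2.

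Genes of mitosis were lower by a smaller amount. Of 33 measured genes 32 were lower, and the list fell by 0.61 on average (camera, adjusted p = 1.19e-09; adjusted p = 0.588 with an estimated correlation). Over the list alone 0 genes passed. Mki67, the proliferation marker, differed by -1.03 (SE 0.33), the spindle checkpoint kinase gene Bub1 by -1.18 (SE 0.37), Birc5 (survivin) by -1.13 (SE 0.36) and the topoisomerase gene Top2a by -1.09 (SE 0.36). The list means were 8.30 and 8.97 in the controls and 7.78 and 8.28 in the mutants, so mutant replicate 2 lay next to control replicate 1. The difference was -0.35 (adjusted p = 0.0087) without mutant replicate 1, -0.27 (adjusted p = 0.0087) without control replicate 2 and -0.97 (adjusted p = 2.38e-15) without control replicate 1.

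Genes of ribosome biogenesis, the nucleolar assembly of ribosomal subunits, moved in the same direction. All 25 measured genes were lower, and the list fell by 0.82 on average (camera, adjusted p = 7.15e-14; adjusted p = 0.456 with an estimated correlation). Npm1 (nucleophosmin) fell 2.41-fold, from 12.28 ± 0.09 (SD, n = 2) to 11.01 ± 0.15 (SD, n = 2), and was the 1 gene that passed when adjusted over the list alone (0 over all probe sets); it did not pass without control replicate 2 or without mutant replicate 2. Gnl3 (nucleostemin) differed by -1.25 (SE 0.36), Dkc1 (dyskerin) by -1.04 (SE 0.34) and the RNA polymerase I subunit gene Polr1b by -1.05 (SE 0.35). Leaving out mutant replicate 1 gave -0.66 (adjusted p = 1.1e-06).

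Among 9 measured inhibitors of cyclin-dependent kinases and retinoblastoma family genes, 4 were higher and 5 lower. The list did not pass (mean 0.19, median -0.11, adjusted p = 0.459). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.53-fold, from 9.86 ± 0.40 (SD, n = 2) to 11.19 ± 0.43 (SD, n = 2), and Cdkn2b, which encodes p15, rose by 1.31 (SE 0.33). These 2 genes passed when adjusted over the list alone (adjusted p = 0.0181 for both) and 0 passed over all probe sets. Neither passed without mutant replicate 1. Cdkn2b alone passed without control replicate 1, and Cdkn1a alone without control replicate 2 or mutant replicate 2.

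Goblet cell genes, which serve mucus production, were higher in the mutants. Of 21 measured genes 16 were higher and 5 lower, and the list rose by 0.56 on average (camera, adjusted p = 1.31e-05; adjusted p = 0.456 with an estimated correlation). Muc2, the main intestinal mucin, rose 2.05-fold, from 11.41 ± 0.27 (SD, n = 2) to 12.44 ± 0.33 (SD, n = 2), and Guca2a, which encodes the peptide guanylin, rose by 1.25 (SE 0.31). These 2 genes passed when adjusted over the list alone (0 over all probe sets). The secretory lineage transcription factor genes Atoh1 and Spdef differed by 0.83 (SE 0.38) and 1.30 (SE 0.49). Klk1, a kallikrein gene, differed by 1.89 (SE 0.66), and 1 of its 3 other probe sets had the opposite sign. Its value was 0.70 without mutant replicate 1, the array with pancreatic transcripts, and 3.02 without mutant replicate 2. Without mutant replicate 1 the list stood at 0.45 (adjusted p = 3.68e-04), and both Muc2 and Guca2a still passed over the list alone; without mutant replicate 2, Clca1 and Klk1 passed in their place. Leaving out control replicate 1 gave a mean of 0.32 (adjusted p = 0.0053) and 0 genes past the test over the list alone; without control replicate 2, 4 did.

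Absorptive enterocyte genes gave a smaller difference whose sign depended on which arrays were kept. Of 35 measured genes 27 were higher and 8 lower, with a mean of 0.30 (camera, adjusted p = 0.00104; adjusted p = 0.669 with an estimated correlation). The list means of the groups overlapped, at 10.53 and 9.47 in the controls and 10.76 and 9.84 in the mutants. In both groups the array numbered 1 stood higher, so leaving out 1 array unbalances the replicate numbers. The mean was -0.16 (adjusted p = 0.813) without mutant replicate 1 and -0.23 (adjusted p = 0.335) without control replicate 2. It was 0.85 (adjusted p = 5.36e-16) without control replicate 1 and 0.74 (adjusted p = 3.87e-10) without mutant replicate 2. The amino acid transporter genes Slc7a9 and Slc3a1 differed by 1.26 (SE 0.30) and 1.17 (SE 0.38), and the brush border protocadherin gene Cdhr5 by 1.03 (SE 0.35). The alkaline phosphatase gene Alpi differed by -0.52 (SE 0.63) and the fatty acid binding protein gene Fabp2 by 0.20 (SE 0.22). Over the list alone 0 genes passed; without control replicate 1, 12 were higher past that test, and without mutant replicate 1, 2 genes (Ada and Alpi) were lower past it.

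Paneth cells, the antimicrobial cells of the crypt base, were covered by 8 measured genes of 22 listed, since most defensin genes had no probe set named for them alone. The list did not pass (mean 0.01, median -0.19, test direction down, adjusted p = 0.726), and the mean was -0.31 (adjusted p = 0.164) without Nupr1, a choice made after seeing the data. Lyz1, the Paneth cell lysozyme, differed by -0.14 (SE 0.18) from a control level of 13.48, and 1 of its 2 other probe sets had the opposite sign, at 0.00 on the log2 scale. The sign turned to 0.25 with the values as deposited and 0.37 with median centring, and the Lyz1 probes can also bind transcripts of the related gene Lyz2. The phospholipase gene Pla2g2a differed by -0.92 (SE 0.46) and the matrix protease gene Mmp7 by -0.47 (SE 0.42). Nupr1, which is also known as a stress response gene, rose 4.85-fold, from 7.03 ± 0.42 (SD, n = 2) to 9.31 ± 0.29 (SD, n = 2), and was the 1 gene past the test adjusted over the list alone (0 over all probe sets), also with each array left out in turn.

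Hormone-producing enteroendocrine cells were represented by 21 measured genes, 13 higher and 8 lower, and the list did not pass (mean 0.29, adjusted p = 0.0908). The list passed without mutant replicate 2 (mean 0.45, adjusted p = 0.0124), which leaves mutant replicate 1 as the mutant array, and stood at 0.14 (adjusted p = 0.749) without mutant replicate 1. In mutant replicate 1 the pancreatic islet genes Ins2 and Iapp were also high, at 9.15 and 10.16, against at most 5.36 and 6.68 in the other arrays. Nts (neurotensin) rose by 2.92 (SE 0.67), the 1 gene past the test adjusted over the list alone (0 over all probe sets); with an array left out it still passed only without mutant replicate 1 (3.94), and Nts stood at 1.84 without mutant replicate 2. The progenitor factor gene Neurog3 differed by -1.43 (SE 0.53), the peptide hormone genes Pyy and Gcg by 1.13 (SE 0.39) and 0.88 (SE 0.35), and Chga (chromogranin A) by 0.27 (SE 0.37). The 11 measured tuft cell genes gave a mean of 0.13 and a median of -0.05 (test direction up, adjusted p = 0.769). The mean was 0.68 without mutant replicate 2 (adjusted p = 0.00457) and -0.41 without mutant replicate 1 (adjusted p = 0.0754). Among them Sh2d6 differed by 0.77 (SE 0.59) and the taste channel gene Trpm5 by 0.63 (SE 0.51).

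**Figure D2:**
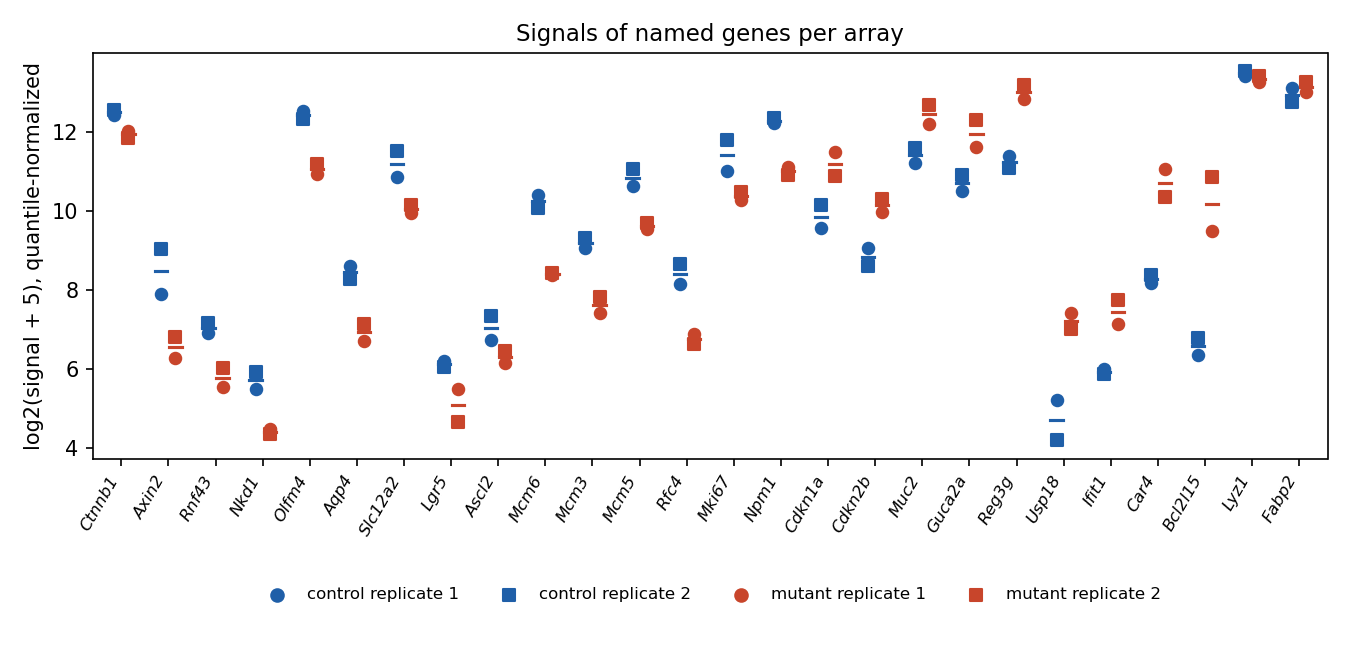
Quantile-normalized log2(signal + 5) of 26 named genes in each of the 4 arrays (points), with horizontal bars for the group means of 2 arrays. Olfm4 and Mcm6 lie lower in both mutant arrays and Muc2 and Reg3g higher, whereas the Fabp2 values of the groups overlap.

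Genes induced by interferon were higher in the mutant crypts. All 18 measured genes were higher, and the list rose by 0.99 on average (camera, adjusted p = 1.15e-09; adjusted p = 0.456 with an estimated correlation). Adjusted over the list alone 4 genes rose, and over all probe sets 0 did. These were Usp18, which removes the ubiquitin-like modifier of interferon signalling and rose by 2.51 (SE 0.46), Oas1a, an activator of viral RNA decay, by 1.93 (SE 0.53), Ifit1 by 1.52 (SE 0.38) and the guanosine triphosphatase gene Igtp by 1.37 (SE 0.41). In the absence of mutant replicate 1 the list stood at 1.31 (adjusted p = 3.22e-15) and 9 genes passed over the list alone, the 4 genes above included. Without mutant replicate 2 the mean was 0.64 (adjusted p = 0.000533). Usp18 was the 1 gene that passed over the list alone without control replicate 2 and without mutant replicate 2, and Oas1a stood at 1.17 in the latter.

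Epithelial antimicrobial and inflammatory genes gave 6 higher and 2 lower of 8 measured, and the list rose by 0.91 on average (camera, adjusted p = 1.94e-04; adjusted p = 0.535 with an estimated correlation). Reg3g, an antibacterial lectin, rose 3.42-fold, from 11.24 ± 0.21 (SD, n = 2) to 13.01 ± 0.24 (SD, n = 2). The chemokine gene Cxcl1 rose by 1.44 (SE 0.39), the oxidase maturation factor gene Duoxa2 by 2.12 (SE 0.72) and Reg3a by 1.72 (SE 0.61). These 4 genes passed when adjusted over the list alone and 0 over all probe sets. The list mean was 0.52 (adjusted p = 0.0338) without mutant replicate 1, 0.43 (adjusted p = 0.055) without control replicate 2, 1.41 (adjusted p = 3.85e-08) without control replicate 1 and 0.32 (adjusted p = 0.114) with no filter on dim probe sets. Of the 4 genes, Reg3g alone still rose over the list alone without control replicate 2 or without mutant replicate 1. Reg3a stood at 2.84 without control replicate 1 and 0.65 without control replicate 2. Duoxa2 stood at 1.31 without control replicate 2 and 1.22 without mutant replicate 1.

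Stress, sterol and immune cell genes moved less, and each of these calls was lost when certain arrays were left out. Immediate early and heat shock genes, which respond quickly to stimulation or tissue handling, were higher for 16 of 19, with a list mean of 0.46 (camera, adjusted p = 0.00538; adjusted p = 0.456 with an estimated correlation). Klf6, an early response transcription factor gene, rose 3.23-fold and was the 1 gene past the test adjusted over the list alone (0 over all probe sets). The list mean was 0.21 (adjusted p = 0.264) without mutant replicate 1, where Klf6 did not pass, 0.44 (adjusted p = 0.055) without control replicate 2 and 0.70 (adjusted p = 0.000133) without mutant replicate 2. Within the list the chaperone gene Hsp90aa1 went the other way, at -0.76 (SE 0.30). Cholesterol synthesis genes were higher for 12 of 15, with a mean of 0.36 (camera, adjusted p = 0.0102; adjusted p = 0.588 with an estimated correlation). Examples were the demethylase gene Cyp51 at 0.96 (SE 0.35), with its other kept probe set at 0.10 (SE 0.36), and the squalene synthase gene Fdft1 at 0.95 (SE 0.39). That mean was 0.43 (adjusted p = 0.0144) without mutant replicate 1, 0.20 (adjusted p = 0.151) without control replicate 1 and 0.29 (adjusted p = 0.141) without mutant replicate 2. Leukocyte markers were higher for 14 of 20, with a mean of 0.43 (camera, adjusted p = 0.0102; adjusted p = 0.588 with an estimated correlation). The members with the smallest p encode antigen presentation proteins that intestinal epithelium can also make, Cd74 at 1.096 (SE 0.371), H2-Ab1 at 0.89 (SE 0.32) and H2-Aa at 1.16 (SE 0.42). The leukocyte mean was 0.09 (adjusted p = 0.687) without mutant replicate 1, 0.17 (adjusted p = 0.468) without control replicate 2, 0.70 (adjusted p = 6.88e-05) without control replicate 1 and 0.77 (adjusted p = 2.79e-05) without mutant replicate 2. Enteric neuron and glia markers, with 3 measured genes, stood at -0.76 (camera, adjusted p = 0.0491; adjusted p = 0.535 with an estimated correlation), with Nos1 at -1.23 (SE 0.46). That call was lost without mutant replicate 1 (-0.55, adjusted p = 0.278), without control replicate 1 (-0.66, adjusted p = 0.201) and without control replicate 2 (-0.85, adjusted p = 0.0609), and also with the pseudocount at the median of all values (-0.54, adjusted p = 0.0559). With no filter on dim probe sets the mean was 0.04.

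Across all 22519 probe sets kept, 0 were higher and 0 lower past an adjusted p of 0.05 by limma, the smallest adjusted p being 0.449. At an unadjusted p under 0.05, 618 were higher and 797 lower. With mutant replicate 1 left out, 7 probe sets were higher and 11 lower past the adjusted threshold, and with mutant replicate 2 left out, 77 and 7. Both mutant values lay above both control values for 3900 probe sets and below them for 4258, together 36.2% of all probe sets, where chance gives 33% for both directions together. The genes named next had the smallest p among those with non-overlapping groups and did not pass. On the higher side, Bcl2l15, a Bcl-2 family gene, had a log2 signal of 6.57 ± 0.31 (SD, n = 2) in controls and 10.18 ± 0.97 (SD, n = 2) in mutants, 12.1-fold higher. Bcl2l15 passed at 4.25 (adjusted p = 0.0102) without mutant replicate 1 and at 2.89 (adjusted p = 0.0322) without mutant replicate 2. The carbonic anhydrase gene Car4 stood at 2.44 (SE 0.35; 2.75 without mutant replicate 2, where it passed with adjusted p = 0.0206), the membrane mucin gene Muc3 at 1.67 (SE 0.27) and the brush border dipeptidase gene Dpep1 at 2.29 (SE 0.43). The gasdermin family gene Gsdmc2 was at 4.38 (SE 0.77), with 5.92 ± 0.60 (SD, n = 2) in controls and 10.30 ± 1.91 (SD, n = 2) in mutants. For Gsdmc2 the difference was 2.96 (adjusted p = 0.0886) without mutant replicate 1 and 5.67 (adjusted p = 1.43e-04) without mutant replicate 2, where it passed. The ammonium transporter gene Rhbg was at 2.13 (SE 0.39), Trim40 at 1.72 (SE 0.34) and Tbcel at 1.66 (SE 0.35), and Reg3g, Nupr1, Usp18 and Klf6 completed the 12 genes. On the lower side, the chromatin helicase gene Hells stood at -1.70 (SE 0.34), the centromere gene Cenpk at -1.97 (SE 0.40), the cohesion gene Esco2 at -1.74 (SE 0.38) and the chromatin gene Dek at -1.31 (SE 0.28). The nucleotide enzyme gene Dctd was at -1.82 (SE 0.36), the uncharacterised gene 2010315B03Rik at -1.76 (SE 0.35) and the secreted Wnt antagonist gene Sfrp5 at -2.27 (SE 0.47). Mcm6, Olfm4, Npm1, Rfc4 and Mcm3 completed the 12 genes.

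The remaining lists fixed in advance did not pass. Components of the Wnt pathway gave 13 higher and 9 lower of 22 (mean -0.07, median 0.21, test direction down, adjusted p = 0.727). Within that list Sfrp5 fell by 2.27 and was the 1 gene past the test adjusted over the list alone (0 over all probe sets); with an array left out it still passed only without mutant replicate 1. The receptor gene Fzd6 differed by -1.002 (SE 0.365). Notch pathway genes had a mean of -0.11 (16 genes, adjusted p = 0.459), with the target gene Hes1 at -0.24 (SE 0.37) and the glycosyltransferase gene Rfng at 1.11 (SE 0.44). Hedgehog and BMP pathway genes had a mean of 0.10 (17 genes, adjusted p = 0.64), with Gli2 at 1.38 (SE 0.40). Intestinal transcription factors had a mean of 0.24 (19 genes, adjusted p = 0.0908; 0.0291 without control replicate 1, 0.0348 with the values as deposited, 0.035 with the brightest 25% of probe sets, 0.0499 with the mean of all probe sets of a gene and 0.0479 with a replicate block), with the bile acid receptor gene Nr1h4 at 1.07 (SE 0.34) and Klf4 at 0.54 (SE 0.46). The means were 0.12 for p53 targets and apoptosis genes (18 genes, adjusted p = 0.459), 0.13 for cell junction genes (22 genes, adjusted p = 0.356; 0.0301 with the values as deposited) and 0.11 for unfolded protein response genes (17 genes, adjusted p = 0.538), of which the pseudokinase gene Trib3 was at 1.49 (SE 0.37). They were 0.24 for fatty acid oxidation and ketogenesis genes (15 genes, adjusted p = 0.197) and -0.0041 for xenobiotic metabolism genes (19 genes, median -0.02, test direction up, adjusted p = 0.572). The fatty acid list passed with the values as deposited (adjusted p = 0.0192), without control replicate 1 (0.43, adjusted p = 0.0115) and without mutant replicate 1 (0.41, adjusted p = 0.029). Mesenchymal and smooth muscle markers had a mean of 0.23 (17 genes, adjusted p = 0.183), which passed at 0.58 (adjusted p = 0.00287) without control replicate 2, and the fibroblast receptor gene Pdgfra was at 1.53 (SE 0.60). The other kept Pdgfra probe set, which was dimmer, stood at 0.09 (SE 0.41). Endothelial and erythroid markers had a mean of 0.17 and a median of -0.0021 (8 genes, test direction up, adjusted p = 0.459). Xenobiotic genes depended on which arrays were kept, at 0.70 (adjusted p = 2.53e-07) without control replicate 1, 0.36 (adjusted p = 0.0445) without mutant replicate 2 and -0.70 (adjusted p = 0.000179) without control replicate 2. The sex-linked list joined Xist, which is transcribed from the inactive X chromosome, at -0.63 (SE 0.24), with the Y-linked genes Eif2s3y at 1.28 (SE 0.40) and Kdm5d at 0.61 (SE 0.49). Because these signs oppose each other, its mean of 0.42 (3 genes, adjusted p = 0.538) decides nothing. Xist was bright in both groups, at a mean log2 signal of 12.16 in controls and 11.53 in mutants. Eif2s3y also had signal in both, at 7.47 and 8.75. Whether the groups differed in sex was not tested.

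Pancreatic digestive enzyme genes, markers of acinar cells, had high signal in 1 of the 4 arrays. In mutant replicate 1 the trypsinogen gene Prss2 had a log2 signal of 13.17 and the carboxypeptidase genes Cpa1 and Cpb1 had 12.70 and 12.67. In the same order mutant replicate 2 had 4.96, 2.84 and 2.89, control replicate 1 had 4.96, 2.56 and 2.63, and control replicate 2 had 4.72, 3.22 and 3.01. The list of 10 genes had a mean difference between groups of 3.76 (camera, adjusted p = 3.88e-05; adjusted p = 0.588 with an estimated correlation). It was -0.37 (adjusted p = 0.192) without mutant replicate 1 and 7.85 (adjusted p = 1.18e-76) without mutant replicate 2.

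**Figure D3:**
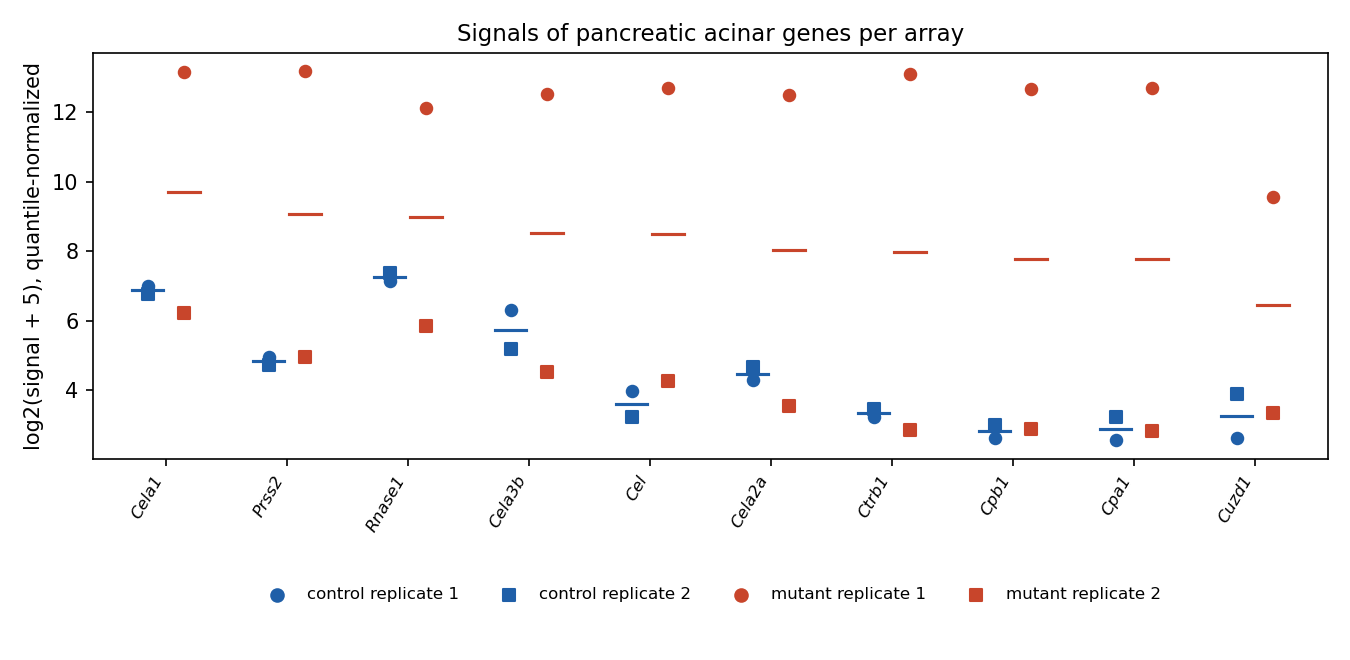
Quantile-normalized log2(signal + 5) of 10 pancreatic acinar genes in each of the 4 arrays (points), with horizontal bars for the group means of 2 arrays. Mutant replicate 1 stands apart from the other arrays, for example at 13.17 for Prss2 against values from 4.72 to 4.96.

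In all, 14 of the 30 lists passed by camera with its preset correlation of 0.01, and 0 with an estimated correlation. With 2 residual degrees of freedom, that loss cannot be put down to correlation between genes alone in every list. The estimated correlation was nonetheless high in some lists, for example 0.741 for mitosis. Where leave-one-out leaves a group with 1 array, that array is assumed to vary like the other group. For any single gene or list mean, 2 arrays against 2 cannot give a two-sided exact permutation p below 0.33.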

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

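The alternatives for lists without shared genes or without Nupr1 were chosen after seeing the data; all others were planned. Against 0 probe sets higher and 0 lower, the values as deposited gave 2 higher, median centring gave 81 higher and 21 lower, and non-overlapping groups with a 2-fold difference and no p gave 509 and 593. Leaving out each array gave 0 to 77 higher and 0 to 11 lower. The 65 genes called with median centring included 9 of the fixed acinar list and 6 acinar genes outside it, and the 48 called without mutant replicate 2 included 10 and 9; other pancreatic genes were not counted. In simulated data 2-fold changes were recovered in 0% of cases and 16-fold changes in 85.9%. Replicate numbers were not taken to pair the arrays, since the labels do not say what they mark and there are only 2 pairs; the correlation of deviations was 0.034 over probe sets, although enterocyte, xenobiotic, mitosis, replication, stem cell, antimicrobial and tuft cell means, among others, shifted the same way by number in both groups. A replicate block gave 1 probe set higher; among lists the block ended the neuron and glia call (adjusted p = 0.0501) and called intestinal transcription factors (adjusted p = 0.0479). The number of lists called, 14, became 0 with an estimated correlation and 0 with fry. The unadjusted camera p rose even where the estimated correlation was below the preset 0.01. It went from 0.0229 to 0.148 for neuron and glia markers (estimated correlation -0.346). For intestinal transcription factors (-0.0441) it went from 0.0464 to 0.163. Higher correlation is therefore not the whole reason in every list. The estimated correlation was 0.741 for mitosis, 0.611 for enterocytes and 0.991 for acinar genes. Higher correlation lowers the camera statistic, so in such lists the loss cannot be set aside as an effect of few degrees of freedom. In lists of low estimated correlation, 2 residual degrees of freedom leave the loss hard to read. Under these tests (estimated correlation, then fry) the adjusted p was 0.456 and 0.28 for the Wnt target (-0.75), stem cell (-0.83) and replication (-0.999) lists, 0.588 and 0.506 for mitosis (-0.61), 0.669 and 0.738 for enterocytes (0.30) and 0.456 and 0.339 for goblet cells (0.56); the causes were not tested beyond the tests' own construction. With arrays left out, list means ranged from -0.89 to -0.63 for Wnt targets, -1.04 to -0.63 for stem cells, -1.24 to -0.78 for replication, -0.97 to -0.27 for mitosis, -0.23 to 0.85 for enterocytes, -0.10 to 0.12 for Paneth cells, 0.32 to 0.80 for goblet cells, 0.14 to 0.45 for enteroendocrine cells, -0.41 to 0.68 for tuft cells, -0.23 to 0.0826 for Wnt components, -0.24 to 0.0285 for Notch, -0.0366 to 0.29 for junctions, -0.70 to 0.70 for xenobiotic genes, -0.13 to 0.58 for mesenchyme and -0.37 to 7.85 for acinar genes. Named genes that changed sign with an array left out ranged from -0.44 to 0.25 (Ephb3), -1.43 to 0.31 (Ccnd1), -1.71 to 0.62 (Alpi), -0.0278 to 0.56 (Chga), -0.11 to 1.13 (Klf4), -1.08 to 0.15 (Mmp7), -0.0608 to 1.63 (Sh2d6), -0.18 to 0.90 (Alox5), -0.0424 to 2.08 (Acaa1b), -0.0498 to 1.57 (Aldh1a1), -0.67 to 0.11 (Vwf), -1.46 to 0.23 (Vip) and -0.0555 to 9.77 (Cpa1). Other reversals, whose cause was not tested, were Lyz1 at 0.25 (as deposited) and 0.37 (median centring); xenobiotic genes at 0.14 (as deposited), 0.26 (median centring), 0.0902 (pseudocount 1), 0.0326 (pseudocount at the median) and 0.0994 (brightest 25%); Wnt components at 0.0335 (median centring) and 0.16 (brightest 25%); Paneth genes at -0.0134 (pseudocount 1), -0.11 (no filter), -0.021 (mean of all probe sets) and -0.31 (without Nupr1); neuron and glia markers at 0.0441 (no filter); and tuft, Hedgehog and unfolded protein response genes at -0.0254, -0.0873 and -0.0842 (brightest 25%). Over all alternatives, single named genes kept their direction and side of the threshold in 1780 cases, reversed in 17 and newly passed in 26. Secondary lists did so in 287, reversed in 21, newly passed in 12 and lost the call in 29.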

Other observations

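Leaving out arrays and adjusting over lists were planned, and the test of acinar genes outside the fixed list was set before its result was seen. The other tests here were chosen after the results were seen. With mutant replicate 1 left out, 7 probe sets were higher and 11 lower past the test, the lone mutant array being assumed to vary like the controls. Among the lower ones in mutant replicate 2 were the iron exporter gene Slc40a1 at -4.16, the calcium-binding protein gene S100g at -4.24, Ada (adenosine deaminase) at -4.73, Enpp3 at -3.83 and Clca4a at -3.94. Among the higher ones were Bcl2l15 at 4.25, Nts at 3.94 and G0s2, a regulator of lipid breakdown, at 3.25. These genes were named after their values were seen, and the values describe mutant replicate 2 alone. The lower genes named here are not among the 12 lower genes above, which required both mutant values below both control values. Alpi, for example, was at 10.29 in mutant replicate 2 but 12.63 in mutant replicate 1, against 12.24 and 11.71 in the controls. The labels do not say which part of the intestine was captured. Xist differed by -0.63 (SE 0.24) and Eif2s3y by 1.28 (SE 0.40) between mutants and controls, and both passed when adjusted over the list of sex-linked genes alone (adjusted p = 0.0406 and 0.0366), while 0 passed over all probe sets and neither passed without mutant replicate 1 or without control replicate 2.

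Digestive enzyme transcripts stood high in mutant replicate 1. The candidate explanation, that this library held RNA from pancreatic acinar tissue, was tested on 15 acinar genes outside the fixed list. Their median lay 3.64 above the mean of the other arrays on the log2 scale, with Ctrl at 12.89 and Sycn at 12.75 in that array, and the islet genes Ins2 and Iapp were 4.67 and 4.08 above it. Of these 15 genes, 3 (Spink1, Clps and Pnliprp2) also had signal above 8 in the other arrays. Deletion of beta-catenin as the cause is argued against by mutant replicate 2, whose median over the fixed list was -0.27 relative to controls; how such RNA may have entered the library was not tested.

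The Wnt target, stem cell, replication and ribosome biogenesis lists were lower in both mutant arrays. RNA integrity or amplification is argued against as the whole cause, because the control stood above the mutant in every one of these lists, by 0.53 to 0.64 where its 5' to 3' ratio was higher and by 0.93 to 1.38 where it was lower. The excess was larger where the control ratio was lower. Within each group, too, the array with the lower ratio had the higher mean in these lists. For replication the means were 9.16 against 8.74 in the controls and 8.12 against 7.78 in the mutants. The mutant ratio was the lower one at each replicate number, so this order would go with higher, not lower, mutant means. The order also follows the replicate number and rests on 2 arrays per group, so the size of any effect of this cause stays open. Pancreatic RNA is argued against as the whole cause, since the difference nearest to 0 without mutant replicate 1 was -0.66, beyond the largest control SD of 0.3. Less crypt base in the captured mutant areas could lower the same genes and stays open. Paneth genes stood 0.84 (SE 0.37) above stem cell genes in their difference, but 0.92 (SE 0.59) without the brightest members and 0.51 (SE 0.19) without Nupr1. These SEs treat genes as independent and leave out the spread between arrays. The 7 Paneth genes left without Nupr1 were themselves lower on average (-0.31). They include Pla2g2a (-0.92) and Mmp7 (-0.47), which are also on the Wnt target list. That fall therefore cannot separate less crypt base from the deletion. The deletion itself is the untested biological explanation.

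The mitosis list is less settled. The same comparisons gave a control excess of as little as 0.02 for arrays of opposite 5' to 3' order, and -0.35 against a control SD of 0.47 without mutant replicate 1. They therefore do not tell RNA integrity or pancreatic RNA apart from the deletion for this list. In both groups the array numbered 2 had the higher mean, and these comparisons are not balanced by replicate number, which keeps the list open. At each number the control mean lay above the mutant mean. Within each group the array with the lower ratio again had the higher mean, 8.97 against 8.30 in the controls and 8.28 against 7.78 in the mutants. That order would go with higher, not lower, mutant means, but rests on 2 arrays per group. Of the 3 splits of the 4 arrays, 1 (the real one) called as many as 14 lists, and the highest other called 10; 3 splits are too few for a share under 0.05. That other split parts the arrays numbered 1 from those numbered 2, with enterocyte genes at -0.99 (adjusted p = 4.2e-21), xenobiotic genes at -1.06 and mitosis genes at 0.59 (adjusted p = 7.33e-09) in arrays numbered 2. It also called 2 of the other lower lists, replication at 0.38 (adjusted p = 0.00129) and stem cells at 0.30 (adjusted p = 0.0359). These stood at -0.999 and -0.83 between mutant and control. Antimicrobial genes were at -0.84 (camera, adjusted p = 0.00262) and leukocyte markers at -0.60 (adjusted p = 3.61e-05), against 0.91 and 0.43 between mutant and control. The remaining split, control 2 and mutant 1 against control 1 and mutant 2, called 4 lists. Among them were interferon genes at -0.51 (camera, adjusted p = 0.000908), against 0.99 between mutant and control.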
